A study of Bacillus subtilis subsp. subtilis str. 168 with 16 samples.

How the data were processed

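Bacillus subtilis cultures of 6 strains, growing exponentially at 37 °C in minimal medium, were fixed with formaldehyde and sonicated, per the labels' protocols. DNA bound by Smc, ScpB or ParB was recovered on antibody-coated magnetic beads, and cleared lysate served as input. The 16 samples form 8 pairs of an immunoprecipitation (IP) and its own input, with 1 library per group. All strains carry an erythromycin marker beside ftsY. Strain groups were taken from the sample titles and genotypes.

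Each of the 8 deposited profiles gives 1 ratio of IP to input for each of 844 bins of 5 kb, as the authors computed it, per the file headers. Reads were aligned with Bowtie, per the submitters' processing notes. Its version, the genome build and the way IP and input libraries were scaled to each other are not given in the sources used here. The profiles carry no read counts, so the depth of each library is unknown and no counting interval could be given. No bin was missing or listed at 0. The submitters' descriptions place the profiles in 3 numbered sets: 698 (ScpB in wild type and in the parB deletion), 1265 (the 3 Smc profiles and ParB) and 1307 (ScpB in both strains with an insertion at amyE).

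The bins run along a chromosome opened near the terminus, with the published coordinate of each bin beside it. For 5 profiles the chromosome was 4215606 bp long. For the other 3 (Smc E1118Q with parS359, ScpB with parS359 and ScpB with mtparS359) it was 1229 bp longer, and bins at amyE were marked as having no published position. The ParB profile, from a strain with an insertion, was on the unmodified chromosome. Bins past amyE in the longer profiles were aligned to the published coordinates of the others by length-weighted means, which blurs values beside sharp peaks. The last bin's published end in the unmodified profiles (2083241) did not match its length of 606 bp, and 2078847 was used.

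Each profile was divided by its own genome median, so a value is a fold over that median and a comparison is a ratio of these values. Scaling removes any genome-wide difference in the recovered amount of DNA. Without it, the median of all bins moved by -0.29 (log2) in E1118Q against wild type Smc, 0.19 in the parB deletion against wild type ScpB and 0.16 in mtparS359 against wild type ScpB. Scaled to the 1 Mb around the terminus, it moved by -0.53, -0.63 and 0.34.

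No genome sequence was used here, so parS sites were not located by their sequence. As fixed for that case before the data were examined, local maxima of the ParB profile at least 3-fold over its median stood in for them. There were 25 such peaks. After the data were examined they were divided into 7 peaks of at least 10-fold without an rRNA gene (the strong peaks), 7 with an rRNA gene and 11 others. Flanking DNA was defined as bins 10 to 100 kb from the nearest peak. The amyE window held the gene's bins and 5 kb on each side. Bins under 0.2 of the genome median in either profile were left out of rankings and of counts of bins. Bins at least 2-fold apart were counted per comparison, as a rule of size and not a test.

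Gene names and neighbourhoods came from a gene table of assembly ASM904v1, all 4536 rows of which had a symbol. Its coordinates are not printed, since the profiles name no build. With that table amyE overlapped both bins marked at the insertion, dnaA lay in the bin marked as origin, and the median of rRNA bins was highest with no shift of the bins. The symbol scpB was not used here, as no row of the table carried it. The 15 gene lists fixed before the data were examined were each placed among 10000 seeded random lists of bins of the same size, drawn from 10 classes of distance from the origin. A list was called apart when its median lay outside the central 95% of these.

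Genes were named by a rule fixed before the data were examined: every ParB peak, the 10 highest regions of each profile, the 10 largest increases and decreases of each comparison, amyE, parB, smc, scpA, scpB, ftsY and dnaA, and the 4 highest members of each list that stood apart. With 1 library per group there was no test between groups and no p-value was computed. The spread over bins between ScpB in wild type and in the strain with the mutated insertion stood in for the spread between libraries, although the pair also differs in numbered set.

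The scripts were tested on simulated profiles of 844 bins. Planted peaks were counted only where their level before noise cleared the 3-fold limit with a margin. Of the 261 counted at 4-fold and 353 at 8-fold, the scripts found 99.6% and 100%, with 0 and 1 false peaks. The simulated background was a smoothed ScpB profile, capped below the 3-fold limit, with small even noise. It left little room for false peaks, so their number does not bear on false peaks in the real ParB profile. Among 200 random lists with nothing planted, 7% lay outside the central 95%. Of 200 lists raised by 0.5 (log2), 99.5% did. These lists held bins drawn singly, whereas many gene lists lie in neighbouring bins. The 7% therefore need not hold for such gene lists. Alternatives covered the scaling, a pseudocount, the peak definition, the width of windows and flanks, the filter on low bins, the 2-fold rule and the random lists. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.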

Results

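Binding of the condensin subunits Smc and ScpB and of the partition protein ParB was profiled along the Bacillus subtilis chromosome by ChIP-seq. The Smc profiles came from wild type, from the ATPase head mutant E1118Q and from E1118Q with the ParB-binding site parS359 inserted at amyE. The ScpB profiles came from wild type, from a parB deletion and from strains with parS359 or a mutated form of it, mtparS359, at amyE. ParB was profiled in the strain with mtparS359. Each profile is 1 IP library over its input in 844 bins of 5 kb, its depth is unknown, and there are no replicates, so every difference below is between libraries and was not tested. Values are folds over each profile's genome median, and positions are the published coordinates given with the bins.

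The first question was where ParB sat. ParB was concentrated in a few sharp peaks near the origin, the highest of them at parA and parB, the genes of the partition proteins (4203848 to 4208847), at 113-fold. The next were at rodA and vpr (3908848 to 3913847) with 82.3-fold and at walK and walR, which encode the regulators of cell wall metabolism (4148848 to 4153847), with 81.5-fold. The bin of gdpP and ppaC (4163848 to 4168847) reached 50.9-fold, that of abrB and metS (43242 to 48241) 43.5-fold, that of nagZ and ybbC (183242 to 188241) 20.1-fold and that of ydaB (468242 to 473241) 11.8-fold. These are the 7 strong peaks. Another 7 peaks lay in rRNA operons, from 4.95-fold at rrnA to 11.5-fold at rrnD, and their reads may be shared among near-identical copies. The other 11 peaks ranged from 3.02-fold at sufC and metN to 7.04-fold at khtS, and included serA, ilvC and ilvB, the gapA to pgm glycolytic operon, the ahpC and katA genes of peroxide defence, mntH, mtnK and rpoC. The median over all 25 peaks was 6.73-fold, above every random list, as the choice of peaks by the ParB profile itself makes certain. The rRNA peaks and the other peaks were also high in ScpB without ParB, at medians of 6.18-fold and 2.20-fold. The strong peaks were at 0.894-fold there, and khtS at 0.907-fold. The rRNA and other peaks may therefore not all mark parS sites, which limits medians over all 25.

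**Figure D1:**
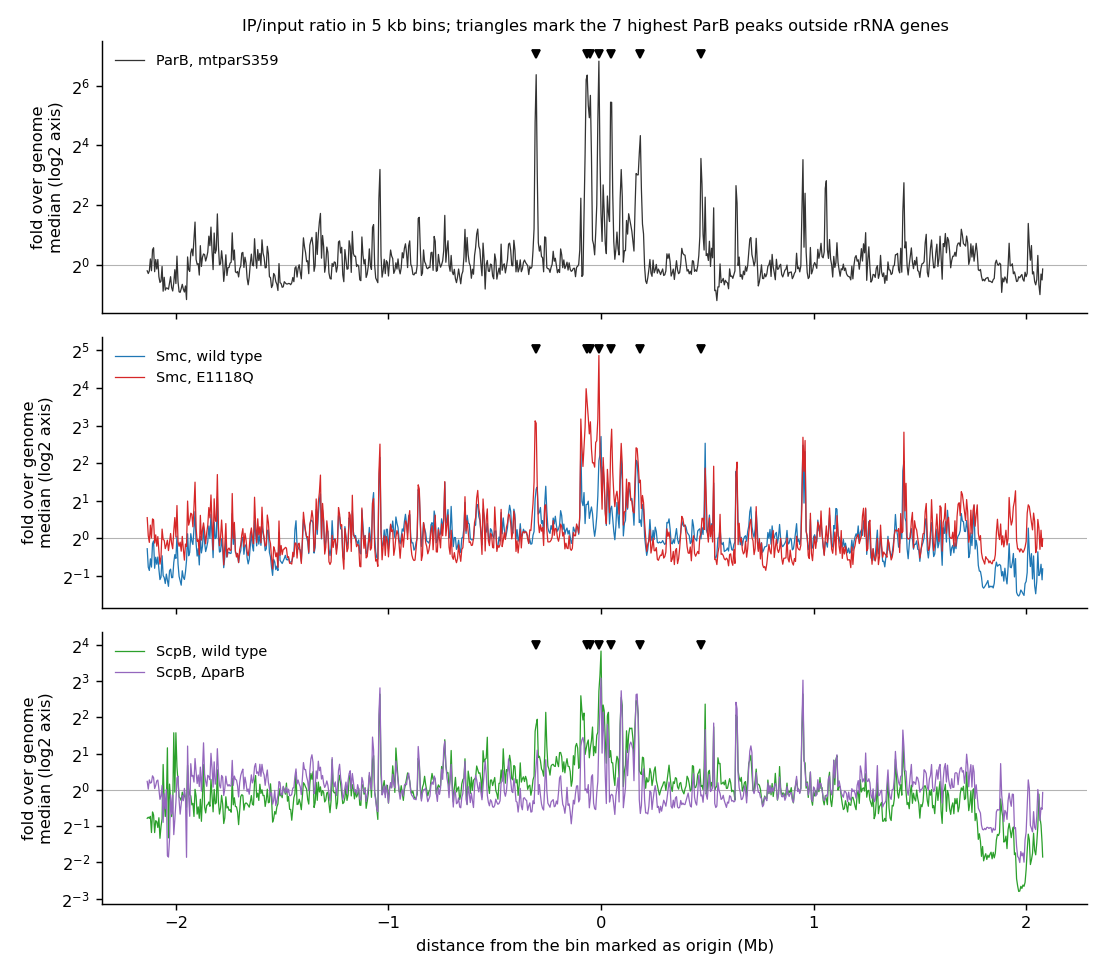
IP/input ratio as fold over the genome median (log2 axis) against distance from the bin marked as origin (Mb), for ParB (top), Smc in wild type and E1118Q (middle) and ScpB in wild type and the parB deletion (bottom), 1 library per line. Triangles mark the 7 strong ParB peaks, where Smc E1118Q reached up to 29.1-fold.

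In wild type, Smc and ScpB were both highest at the origin, in the bin of dnaA, the replication initiator, and dnaN (4213848 to 3241), with 6.53-fold and 14.2-fold. Both were also high at ahpC and ahpF (5.64-fold for Smc and 6.05-fold for ScpB) and at kimA and mntH (5.77-fold and 5.15-fold). Smc was high at katA, which encodes catalase (4.94-fold), where ScpB was at 1.67-fold. Over the 100 kb on each side of the origin the median was 1.81-fold for Smc and 2.56-fold for ScpB, against 0.725-fold and 0.676-fold in the 1 Mb around the terminus. Across 835 bins, which are not independent replicates, Spearman's rho between the wild-type profiles was 0.81 and Pearson's r of log2 values 0.84. The profiles came from different numbered sets.

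The E1118Q comparison asks how the ATPase heads affect targeting to ParB sites. Smc E1118Q was higher than wild type at 6 of the 7 strong peaks by at least 2-fold: 6.96-fold at parB (29.1 against 4.19), 6.47-fold at walK, 5.28-fold at gdpP, 3.36-fold at rodA, 2.90-fold at abrB and 2.08-fold at nagZ. At ydaB the ratio was 1.11. The largest ratio of any bin, 8.47-fold, was beside walK at the arginine catabolism genes rocD and rocE (4143848 to 4148847). This bin is part of the same ParB peak: over it and the walK bin together, ParB had a mean of 77.3-fold. The origin bin of dnaA, by contrast, held 3.32-fold in E1118Q and 6.53-fold in wild type, a ratio of 0.508. Over all 25 peaks, the comparison fixed before the data were examined, the median ratio was 1.32-fold (log2 0.40), with 23 of 25 above 1. The strong peaks, set apart after the data were examined, had a median of 3.36-fold (log2 1.75), the rRNA peaks 1.26-fold and the other peaks 1.36-fold. The median over all 25 turned to 0.914-fold when profiles were scaled to the terminus, where E1118Q was the higher (median 1.52-fold), while 6 of the 7 strong peaks stayed above 1.

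On flanking DNA, the mean log2 ratio of E1118Q to wild type over bins 10 to 100 kb from a peak was -0.05 ± 0.40 (SD over 426 bins). Around the strong peaks the mean log2 ratio was 1.77 at the peak, 1.23 within 10 kb, 0.58 from 10 to 20 kb, 0.13 from 20 to 50 kb and -0.15 from 50 to 100 kb. In all, 57 bins were at least 2-fold higher in E1118Q, 20 of them within 100 kb of the origin and 31 around the terminus, such as those of xynD (4.04-fold) and oxdD (3.29-fold). The 2 bins at least 2-fold lower held kinE and mtnA (0.327) and aprE, the subtilisin gene (0.424). The split of higher to lower bins depended on the scaling: it was 28 to 4 as deposited and 21 to 41 scaled to the terminus. Among the gene lists, the flagellum and chemotaxis genes were at 1.90-fold in E1118Q and 1.37-fold in wild type. Their median ratio (log2 0.48) and that of the rRNA genes (1.27-fold, log2 0.35) lay above the range of random lists. Scaled to the terminus, the flagellar ratio was -0.04 and that of the rRNA bins -0.18.

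**Figure D2:**
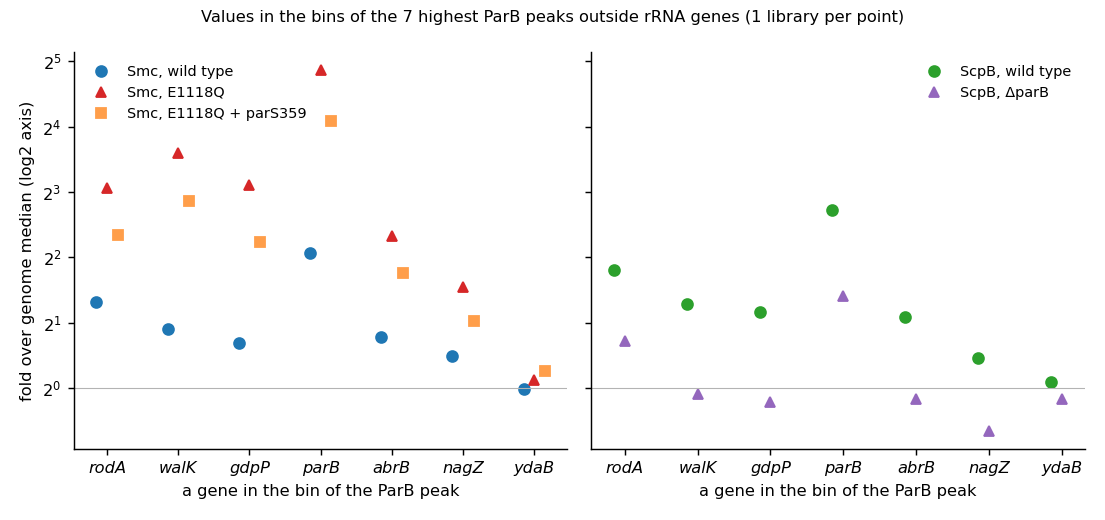
Fold over the genome median (log2 axis) in the bins of the 7 strong ParB peaks, each labelled by a gene in its bin, for Smc (left) and ScpB (right), 1 library per point. Smc E1118Q lies above wild type, from 1.11-fold at ydaB to 6.96-fold at parB, and ScpB in the parB deletion lies below wild type at each of the 7.

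The parB deletion asks whether condensin at these sites depends on ParB. ScpB without ParB was lower at the strong peaks: 0.383 of wild type at gdpP, 0.386 at walK, 0.422 at abrB, 0.461 at nagZ and 0.472 at rodA, with 0.834 at ydaB. The bin of parB itself, part of which is deleted, was at 0.402 and was left out of the medians. ScpB at ahpC was at 6.05-fold in wild type and 2.30-fold in the deletion, the tagA to tagE teichoic acid genes were at 0.331 and the origin bin of dnaA at 0.596. The lower values were not limited to peaks: within 100 kb of the origin the median was 0.536, and 10 to 100 kb from a strong peak the mean was 0.632. Around the terminus the deletion was the higher, with a median of 1.62-fold. The rRNA genes had a median ratio of 1.02.

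The median over the 24 peaks outside parB, the comparison fixed before the data were examined, was 0.919 (log2 -0.12), which was higher than in 98.5% of random lists at the same distances from the origin. Its sign depended on the setting: it was 0.07 as deposited, 0.13 with 2-fold peaks and -0.75 scaled to the terminus (log2). Over the 6 strong peaks outside parB it was 0.441 (log2 -1.18), lower than in all but 0.67% of random lists, while the rRNA peaks were at 1.13-fold (5 of 7 above 1) and the other peaks at 1.03-fold (6 of 11 above 1). Scaling to the terminus lowers every log2 ratio of this comparison by 0.63, which took the rRNA bins from 0.14 to -0.49. In all, 49 bins were at least 2-fold lower, 42 of them within 350 kb of the origin and 5 in the prophage SP-beta. Another 16 were at least 2-fold higher, all around the terminus, such as that of the glutamate synthase genes gltA and gltB (2.82-fold). The highest ratio, at yobO (3.43-fold), came from the last bin, which is only 606 bp long. Wild type was at 0.277-fold there, near the 0.2 limit for low bins. The split of higher to lower bins was 47 to 28 as deposited and 1 to 215 scaled to the terminus. The SP-beta bins were uneven in both libraries of set 698.

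The insertion at amyE asks whether parS is enough to bring condensin to a new place. With parS359, Smc E1118Q was 7.83-fold higher in the amyE window (318242 to 338241) than in E1118Q without an insertion, and 20.6-fold higher in the bin of amyE and the lactate genes lctE and lctP (0.652 to 13.4). The highest of 837 other windows was at 1.78-fold, beside the insertion. No E1118Q strain carried mtparS359, so this comparison does not separate parS359 from the insertion itself. Its 2 profiles also lie on chromosomes of different length. ScpB in cells with wild-type Smc was 1.54-fold higher with parS359 than with mtparS359 (log2 0.63) and 1.90-fold in the amyE bin (1.13 to 2.16). The highest of 837 other windows was at 1.37-fold, starting at 198242. With 20 kb on each side, however, 2 of 825 other windows were as high for ScpB. The highest, starting at 233242, was at log2 0.39 against 0.37 at amyE. Both starts lie in the raised stretch on the origin side of amyE described below. With mtparS359 the window stayed near the level of wild type for ScpB (1.02-fold), and ParB there was at 0.995 of its median, on a chromosome without the inserted sequence.

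Elsewhere, Smc E1118Q was lower with parS359 at amyE than without at 6 of the 7 strong peaks, with a median of 0.611, from 0.552 at gdpP to 0.701 at nagZ, while ydaB was at 1.09. Over all 25 peaks the median was 0.896, with 9 above 1 and 16 below, and the rRNA peaks were at 1.28-fold (7 of 7 above 1). At the strong peaks, ScpB with parS359 was at a median of 0.993 of the mtparS359 strain. Over all 25 peaks its median was 1.06-fold, with 17 above 1 and 8 below, and at the rRNA peaks 1.08-fold (7 of 7 above 1). Smc E1118Q had 7 bins at least 2-fold higher with parS359 and 0 lower. Of these, those of gmuC (2.31-fold) and kinE (2.31-fold) lie beside sharp peaks past amyE, where the alignment of the longer chromosome blurs values. ScpB had 0 bins 2-fold apart in either direction. It was higher with parS359 in all 25 bins on the origin side of the window (193242 to 318241), with a mean of 1.28-fold, and by a mean of 1.05-fold in the 25 bins on the other side.

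**Figure D3:**
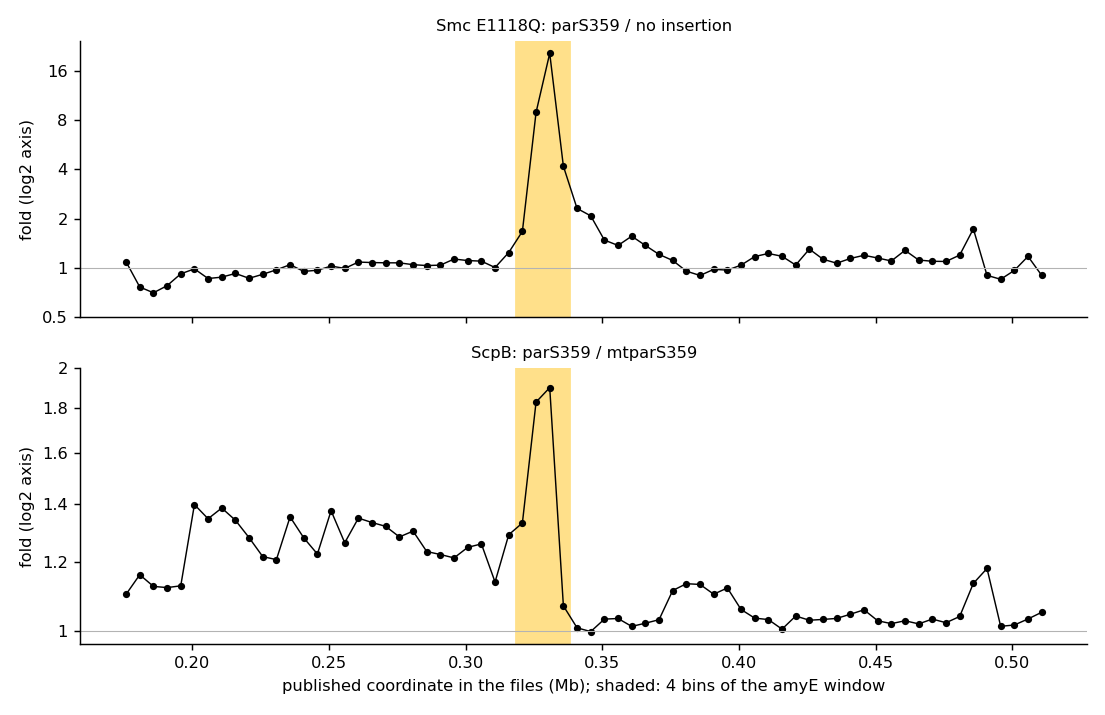
Fold (log2 axis) against published coordinate (Mb) around amyE, for Smc E1118Q with parS359 over no insertion (top) and ScpB with parS359 over mtparS359 (bottom), 1 point per bin. The shaded amyE window holds the highest values, up to 20.6-fold for Smc E1118Q and 1.90-fold for ScpB.

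ScpB with mtparS359 and ScpB in wild type differ by an inactive insertion and by numbered set, and stand in for the spread between libraries. The SD over bins of their log2 ratio was 0.36, and 0.25 without rRNA and SP-beta bins. The strong-peak differences of E1118Q and of the parB deletion, except at ydaB, were larger than this SD, and so were both differences in the amyE bin. For single bins 1 SD is a low bar, and it comes from ScpB alone. Within this pair the bin of ydaM, past amyE and beside the mntH peak, was higher with mtparS359 by log2 0.95. ScpB in the amyE bin differed by 0.93, a similar size. The ydaM bin lies where the alignment of the longer chromosome blurs values, however, so it is a poor measure of the spread between libraries. The 2 profiles compared at amyE share their numbered set and chromosome length, and the SD over bins of their log2 ratio was 0.15. The next highest region of that pair was at 1.47-fold, against 1.90-fold in the amyE bin. With 1 library each, their difference was not tested. No bin was 2-fold higher with mtparS359 and 26 were lower, 23 of them in rRNA operons or SP-beta, such as rrnD (0.344), rrnB (0.347) and the bin of yorR (0.168). The split of higher to lower bins was 2 to 14 as deposited and 3 to 12 scaled to the terminus. The bin of katA was higher with mtparS359, by 0.85 (log2).

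Gene groups differed along all profiles. The rRNA genes were the highest list in each, from 2.07-fold for ScpB with mtparS359 to 5.58-fold for ParB. Of the 59 placements of a list in a profile outside the central 95% of random lists, 38 were also outside it and 21 were not when each list was placed among its own rotations along the chromosome. Those lost included glycolysis and PBSX for wild-type Smc and ScpB, and amino acid synthesis and ICEBs1 for wild-type Smc. Another 5 were outside it only among rotations. Ribosomal protein genes stood above 99.5% of random lists in wild-type Smc (1.39-fold) and above 99.86% in wild-type ScpB (1.69-fold). The purine and pyrimidine synthesis genes were at 1.65-fold and 1.57-fold, and the glycolysis genes at 1.46-fold and 1.44-fold. Amino acid synthesis genes were at 1.24-fold for Smc, above 99.955% of random lists. For ScpB they were at 0.842-fold in wild type, inside the range, but above it in the parB deletion (1.21-fold), with mtparS359 (1.01-fold) and with parS359 (0.990-fold). Among rotations, the deletion, mtparS359 and parS359 placements all lay inside the range, above 97.2%, 51.2% and 48.9% of them. The prophage PBSX was at 0.704-fold for Smc and 0.580-fold for ScpB, and the mobile element ICEBs1 at 0.744-fold for Smc but at 1.08-fold for ScpB, inside the range of random lists. Lists for tRNA genes outside rRNA bins (1.27-fold for Smc), ATP synthase (1.69-fold), late sporulation (0.918-fold), competence (1.02-fold), SP-beta (0.536-fold) and the segregation loci (log2 0.13) lay inside the range of random lists for wild-type Smc, and RNA polymerase and translation factor genes (1.71-fold) above it. Of the segregation loci, the shared bin of smc and ftsY was at 0.826-fold and scpA at 0.784-fold.

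**Figure D4:**
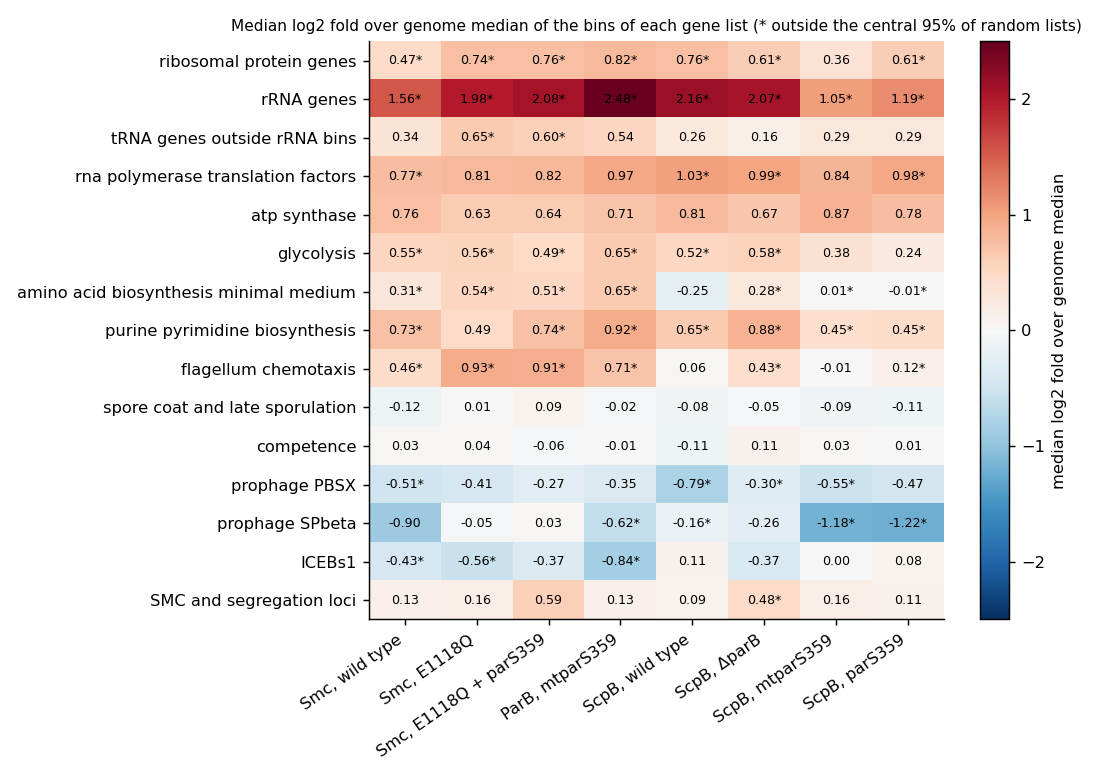
Median log2 fold over the genome median of the bins of each of 15 gene lists (vertical) in 8 profiles (horizontal), with colour and number giving the same value and an asterisk for lists outside the central 95% of random lists. The rRNA genes hold the highest value in each profile, 2.48 for ParB.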

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

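The strong-peak, SP-beta, rRNA-free, bin-number and flagellar alternatives were chosen after the data were examined, and the rest before. With no replicates and no counts, a value was held to have moved when it changed by more than 0.36 (log2), the SD over bins between ScpB with mtparS359 and in wild type. Counts were held to have moved beyond 1.5 times. Of the 87 values recomputed for the main results, 6 could not differ by construction (scaling for the spread and the lists, a filter that removed no bin). Of the other 81, 56 stayed within these limits, 24 moved and 1 with a main value above 0.36 changed sign. Of the 56, 5 with a smaller main value changed sign: ScpB without ParB, to 0.07 as deposited and 0.13 with 2-fold peaks, and the flanking mean in 3 settings, to at most 0.08. Of 198 for single bins and groups, 26 moved and 1, the flagellar ratio, changed sign from above 0.36, to -0.043 scaled to the terminus. Counting smaller main values too, 19 of the 198 changed sign, 14 of them within the limit. Beyond it, besides the flagellar ratio, were ydaB, katA and the rRNA bins for E1118Q and the rRNA bins for the parB deletion, all scaled to the terminus. No paired analysis was possible because each group has 1 library. The motif-bin and 1-mismatch alternatives were not run, since no genome sequence was used here. What depth limits is unknown.

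Scaled to the terminus, E1118Q over wild type Smc at all peaks changed sign, to -0.13, its flanking mean moved to -0.57 and ScpB without ParB moved to -0.75. E1118Q is higher than wild type at the terminus, which that scaling removes by construction. With the strong peaks, ParB moved to 5.67, E1118Q over wild type to 1.75 and ScpB without ParB to -1.18. ParB at peaks was 1.49 as deposited, 1.96 as the mean of 3 bins and 1.72 with 2-fold peaks. Smc E1118Q at amyE was 3.77 with 1 kb and 1.996 with 20 kb on each side. The ScpB value at amyE, its spread and the ScpB and Smc correlation stayed within the limits where they could differ. The count of lists was 43 with rotations, 38 of them shared with the 59.

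Bins 2-fold apart for E1118Q numbered 32 as deposited, 161 at 1.5-fold and 19 at 3-fold, against 59. For the parB deletion they numbered 216 scaled to the terminus, 271 at 1.5-fold and 8 at 3-fold, against 65. For parS359 in E1118Q they numbered 27 and 3 at these folds, against 7, and for ScpB with parS359 2 at 1.5-fold, against 0. For mtparS359 against wild type they numbered 16 as deposited, 15 scaled to the terminus, 69 at 1.5-fold, 5 at 3-fold and 3 without SP-beta and rRNA bins, against 26. Apart from the terminus scaling and the stricter or looser folds, the cause was not tested.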

Other observations

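All tests below were chosen after the results were seen, except that of the PerR regulon. ScpB in the strain with mtparS359 was at 3.67-fold in the bin of dltB to dltE, genes that modify teichoic acids. The bins on each side of the ParB peak at rodA were at 3.47-fold (sacT and vpr) and 3.38-fold (qoxA to qoxD, of the terminal quinol oxidase). Without ParB the 10 highest ScpB regions were the origin bin of dnaA, 7 rRNA regions, the trnS tRNA cluster (3.59-fold) and the bin of kimA and mntH (3.16-fold). Away from peaks, rRNA and SP-beta, Spearman's rho across 640 bins between ParB and Smc was 0.73 in wild type and 0.81 in E1118Q, profiles of the same numbered set. It was 0.35 between ParB and ScpB in wild type and 0.64 between ParB and ScpB without ParB, from another set.

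The ahpC and katA bins, genes of the peroxide-sensing PerR regulon, were among the highest of wild-type Smc. The hypothesis that the whole regulon shares this level was tested on its other genes, 9 of them in 5 bins. In ScpB with mtparS359 their median lay above 92.9% of random lists, inside the central 95% of them, the limit set beforehand, so these data do not show a level common to the regulon. Over the 8 profiles the highest placement was that of wild-type Smc (1.33-fold), above 96.1% of random lists and also inside the limit.

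The rRNA bins of ScpB were lower in set 1307 than in set 698, with a median log2 ratio of mtparS359 to wild type of -1.15 over 17 bins. The insertion at amyE is common to both strains of set 1307, but in Smc E1118Q the 13 rRNA bins before amyE were higher with an insertion (median 0.22, 13 of 13 above 0), which argues against it, as far as Smc E1118Q stands for ScpB. The 29 bins of ribosomal protein, RNA polymerase and translation factor genes, transcribed strongly but not repeated, had a median of -0.21, above 3.62% of random lists. Taken singly, both lists lay below the central 95%, the ribosomal protein genes at -0.23 (above 1.4%) and the RNA polymerase and translation factor genes at -0.42 (above 0.52%). The tRNA genes outside rRNA bins were at a median of 0.907 of wild type, inside the range of random lists. Of their 13 bins, 3 were above wild type and 1 was at least 2-fold lower. The latter, the trnS tRNA cluster, was at 0.438 (log2 -1.19), near the median of the rRNA bins. Held to the limit first set, within 0.36 of 0, the -0.21 would have favoured a different treatment of reads shared between rRNA copies in the 2 sets. Held to random lists, a limit chosen after the result was seen, it was neither supported nor excluded.

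ScpB was uneven along the prophage SP-beta in both libraries of set 698, from 0.397-fold to 2.98-fold in wild type. The SD of log2 steps between neighbouring bins was 2.66 times that outside in wild type and 2.14 times in the parB deletion, against at most 0.793 times in the ScpB libraries of set 1307. In wild type, 4 of the 5 bins that share their exact ratio with another bin lie in SP-beta, but in the parB deletion 0 of 2 do. If the signal were binding that needs ParB, the strain with mtparS359, where parB is intact, should resemble wild type. SP-beta was lower there than in wild type by a median log2 ratio of -0.98, against -0.27 in the 20 bins on each side. That library is from set 1307 and wild type from set 698, so the comparison cannot separate a need for ParB from the difference between sets. Few reads behind these bins may account for the unevenness, though no counts are given with the profiles, and a loss of the prophage from those cells was not tested.

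ScpB was higher with parS359 than with mtparS359 on the origin side of amyE, the mean log2 ratio over 25 bins there exceeding that on the far side by 0.29. Of 737 other positions, 0.136% had a difference as large, the highest of them 0.29, but they hold only 13 positions without overlap, so slow drift between the libraries was not excluded. In Smc E1118Q the difference had the opposite sign, -0.28, with the far side higher, and 4.48% of other positions had one as large. E1118Q need not behave as wild-type Smc, so an effect of the active site was not excluded either, and 1 library on each side leaves the pattern unexplained.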
